A study of Mus musculus with 5 samples.

How the data were processed

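Gene expression was measured in mouse gastric organoids, cell clusters grown from stomach epithelium, on 5 one-colour Agilent arrays, 1 per sample. The control was an organoid line from mice whose Trp53 gene is flanked by loxP sites, carrying the empty hairpin vector with a luciferase hairpin and taken before injection under the skin. The other 4 samples were organoids grown out of subcutaneous tumours. The labels do not say whether these tumours grew from the control line. 2 of them combined Trp53 loss with a hairpin against Cdh1 (hairpin 1 and hairpin 2, group shCdh1), 1 combined Trp53 loss with the Apc lesion named in the labels, and 1 combined Trp53 loss with an activating Pik3ca mutation. The design text counts more tumour-derived organoids than the 4 in these files, and the others were not analysed here. Groups were taken from the sample descriptions alone. The pair of hairpins was treated as 2 replicates of 1 group. Nothing in the labels says whether they came from separate cultures or animals, so every limma p-value for a single gene measures only the spread between these samples, part of which may be technical.

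Per the labels' protocols, total RNA was column-purified and labelled with Cy3 by a low-input amplification kit. Per the submitters' processing notes, spots were quantified with Agilent Feature Extraction 11.0.1.1. The deposited scanner files give, per the file headers, the processed signal of each spot as an intensity that the software had already background-subtracted and spatially detrended, without normalization between arrays, together with median spot and local background intensities. The authors' deposited value table is on a log2 scale. Set against the scanner values, its differences between each tumour-derived array and the control had a slope of 1 and a correlation of 1 over 53335 probes, with constants between −0.046 and −0.023, so its direction and 75th-percentile scaling are settled, while the baseline subtracted from each probe stays unknown. Its column medians were −0.057 for the control, 0.074 and 0.031 for hairpins 1 and 2, −0.08 for Apc and 0.022 for Pik3ca.

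For each array the log2 processed signal was reduced by the 75th percentile of the 59305 non-control spots, so that a level of 0 is the array's 75th percentile. Control spots were left out, as were spots marked by the software as outliers (78 to 114 per array). No spot was saturated. Repeated spots of a probe were averaged, and 32 of 56605 probes without a usable value on every array were dropped. Probes were named through their transcript accession and a RefSeq gene table of assembly GRCm38.p6, used for names only. 34549 probes matched 1 gene symbol and 22024 did not. A gene with several probes was represented by the probe with the highest mean signal. Among 7461 such genes, 25 had probes that moved over 2-fold in opposite directions. Of 23779 genes, 17583 with any probe well above background on at least 1 array were tested. The probe used was well above background on all 5 arrays for 14581 of them and on none for 29. Between 61.8% and 65.3% of spots were well above background, and the 75th percentile of signal was 24 to 27.9 times the median local background. The number of arrays limits the precision. No genome was used, so probe positions are not given.

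7 comparisons were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, and every adjusted p for a single gene is from limma. The 4 tumour-derived arrays were compared with the control in a fit with 1 term and 3 residual degrees of freedom, in which the lone control is assumed to vary like the tumours. Each genotype was compared with the control, and each with the mean of the other tumour genotypes, in a fit with 1 mean per group. That fit has 1 residual degree of freedom, from the pair of hairpins, and the single arrays of the other groups are assumed to vary like that pair. Errors given after ± are standard errors of these fits. Gene names are skipped where they are clone-type names. Named genes are the 10 highest and 10 lowest differences among passing genes well above background on every array of both sides, filled up with the largest differences that did not pass, and the 5 per direction with the largest lower-bound fold. In the all-tumour comparison this rule named a gene only if all 4 tumour-derived arrays lay on the same side of the control. For comparisons of single genotypes the naming stopped at 5 per direction. Some genes that the rule names were left out of the text. The 4 targeted genes and up to 4 members per gene list, those with the largest differences among members well above background on all 5 arrays, were also named. A gene well above background on one side and on no array of the other has only a lower bound, written "at least". It was computed against the higher of the gene's own signal and the lowest signal among probes well above background on each array.

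31 gene lists were fixed before the data were examined. They were p53 targets, epithelial junction and keratin genes, mesenchymal genes, Wnt targets, FoxO targets, sterol and fatty acid synthesis, glycolysis, hypoxia, cell cycle, markers of pit, mucous neck, chief, parietal and endocrine cells, gastric stem and progenitor markers, spasmolytic metaplasia genes, intestinal and squamous epithelial markers, markers of fibroblasts, leukocytes, endothelium and adipocytes, interferon-stimulated genes, antigen presentation, NF-kB and chemokine genes, YAP targets, Notch targets, immediate early and stress genes, Ras-ERK feedback genes, xenobiotic and glutathione genes, and matrix protease genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists of a comparison, and again with an estimated correlation. At the preset correlation camera sets a list's genes against the other genes, so its p does not measure how the list varies between samples. With the estimated correlation 0 lists were called in any of the 7 comparisons, and 1 list, the p53 targets in all tumour-derived samples against the control, had an unadjusted p below 0.05. That test rests on the residual degrees of freedom, 3 in the all-tumour comparison and 1 in the genotype fit. So few leave it little power, and its lack of calls decides nothing about a list. With fry, which asks whether a list's genes move one way on balance and does not set them against other genes, 8, 4, 5, 7, 2, 3 and 1 lists had an unadjusted p below 0.05 in the 7 comparisons in the order reported. Each list's median was also placed among 10000 random lists of the same size matched on mean signal. 11 further lists were written after values had been seen and serve the closing observations only.

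The control and both shCdh1 arrays were on slide 1, scanned together, and the Apc and Pik3ca arrays were on slide 2. Slide and genotype cannot be told apart in the Apc and Pik3ca comparisons with the control, or in the shCdh1 comparison with the other tumours. The all-tumour comparison was refitted with slide as a block, and the Apc and Pik3ca comparisons with the other tumours were set beside the difference within slide 2. Slide 2 holds no control, so the blocked differences are those of shCdh1 against the control on slide 1. They adjust nothing for the Apc and Pik3ca arrays. The other settings tried were normexp background correction (offset 50) on median spot signals, which stand in for the mean signals these files lack, quantile normalization, no filter on dim genes, only genes well above background on all 5 arrays, a floor at the lowest signal well above background, the mean over a gene's probes, an intensity trend in eBayes, a 2-fold minimum, the authors' value table, and each tumour-derived sample left out in turn.

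The fits were tested on simulated data for all 17583 genes. All 5 arrays, the control included, were drawn with the same normal spread per gene, taken from the fitted prior. The simulation therefore cannot test whether the lone control varies like the tumours, or how signals near background behave. In the all-tumour comparison 0%, 9.6%, 70.6% and 84% of genes changed by 1, 2, 4 and 6 on the log2 scale were recovered, with 48 false calls among 869. In the genotype fit, simulated for shCdh1 against control, Apc against control and Apc against the other tumours, 0% were recovered at each of these sizes. Between 4.98% and 5.06% of unchanged genes had an unadjusted p below 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.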

Results

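Expression of 17583 genes was measured in 5 mouse gastric organoid samples, 1 array each. The reference was the control organoid line carrying a luciferase hairpin, taken before subcutaneous injection. The 4 others were organoids recovered from subcutaneous tumours: shCdh1 hairpins 1 and 2, Apc and Pik3ca, all with Trp53 loss. Levels are log2 signal relative to each array's 75th percentile. Between 36661 and 38710 of 59305 spots per array were well above background. Only the shCdh1 group had replicates (n = 2), so single arrays of the other groups have no replicate check of their own. Because the labels describe the control as a line with the floxed Trp53 gene and name no Trp53 loss for it, every contrast with the control combines Trp53 loss, the second lesion, and growth and recovery as a tumour. Any difference of donor animal or organoid line enters these contrasts as well, as does slide for Apc and Pik3ca.

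The genes targeted by the design were examined first. Cdh1, which encodes the epithelial adhesion protein E-cadherin, had a log2 level of 4.39 in the control, 0.07 and 0.26 with hairpins 1 and 2 (20-fold and 17.6-fold lower than the control), 4.48 in Apc and 4.58 in Pik3ca. Trp53, which encodes the tumour suppressor p53, stood at 0.85 in the control and at −5.06, −5.09, −5.86 and −4.86 in hairpin 1, hairpin 2, Apc and Pik3ca, which is 60.5-fold, 61.6-fold, 105-fold and 52.3-fold lower. Whether the Trp53 probe lies inside the deleted part was not checked, since no genome was used. Apc, which encodes a scaffold of the β-catenin destruction complex, was at −2.89 in the control and −3.24 in the Apc tumour, within the −2.97 to −3.36 of the other tumours. Pik3ca, which encodes a catalytic subunit of PI3-kinase, was at 3.40 in the control and 2.23 in the Pik3ca tumour, against 2.97, 2.33 and 1.45 in the others. The Apc and Pik3ca probes report transcript level only and check nothing about either lesion.

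**Figure D1:**
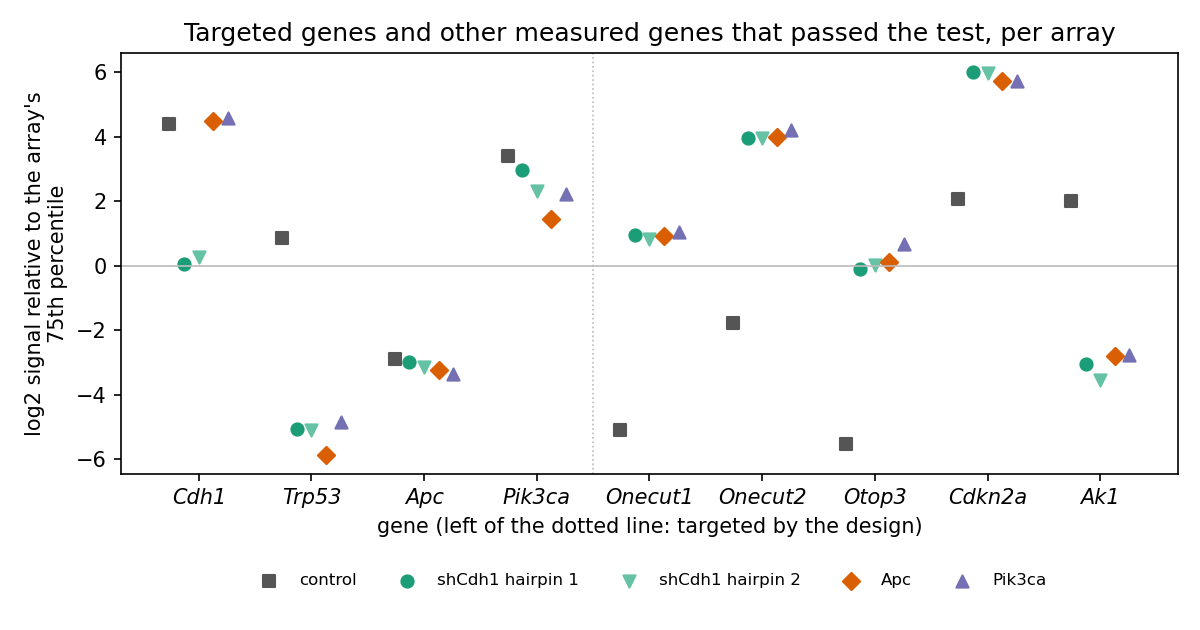
Log2 signal relative to the array's 75th percentile (vertical axis) of the targeted genes Cdh1, Trp53, Apc and Pik3ca and of the other measured genes that passed the all-tumour test (Onecut1, Onecut2, Otop3, Cdkn2a and Ak1), 1 marker per array for the control, shCdh1 hairpins 1 and 2, Apc and Pik3ca. Cdh1 lies at 0.07 and 0.26 in the shCdh1 arrays and between 4.39 and 4.58 in the rest, and Trp53 lies at 0.85 in the control and between −5.86 and −4.86 in the tumour-derived arrays.

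The arrays correlated at 0.951 to 0.976 across genes, which are not independent replicates. Hairpins 1 and 2 correlated at 0.973 and differed at least 2-fold in 2325 genes, 1189 of them well above background on both arrays. Hairpin 1 and the Pik3ca tumour differed at least 2-fold in 2047 genes and hairpin 2 and the Apc tumour in 2158, both fewer than the hairpin pair. Among genes well above background on both arrays these counts were 1057 and 1031. By these counts each hairpin lay closer to another genotype than to the other hairpin, although their pair gives the spread of the genotype fit. By correlation this held for hairpin 1 (0.976 with Pik3ca) but not for hairpin 2 (0.97 with Apc and 0.971 with Pik3ca). The control differed at least 2-fold from hairpin 1, hairpin 2, Apc and Pik3ca in 3047, 3407, 3131 and 3880 genes. All samples are labelled female. Xist, the transcript of the inactive X chromosome, was between −0.90 and −0.69 in the control, both hairpins and Apc and not well above background in Pik3ca (−8.14), where the Y-linked genes Ddx3y (−2.40), Eif2s3y (1.35), Kdm5d (−1.86) and Uty (−3.15) were well above background, as in none of the other 4 samples.

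The first comparison asked what all 4 tumour-derived samples had in common against the control. Onecut1 and Onecut2, homeodomain transcription factors of the developing liver and pancreas, rose 65.5-fold (log2 6.03 ± 0.21, adjusted p = 0.00574) and 56.1-fold (5.81 ± 0.22, adjusted p = 0.00574). Otop3, a proton channel of the otopetrin family, rose 52.1-fold (5.70 ± 0.36, adjusted p = 0.0221), and Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf, rose 13.9-fold (3.80 ± 0.23, adjusted p = 0.021). Trp53 fell 67.3-fold (−6.07 ± 0.43, adjusted p = 0.0344) and Ak1, an adenylate kinase, 33.3-fold (−5.06 ± 0.36, adjusted p = 0.0353). The naming rule required each of these 6 genes to lie on the same side of the control in 4 of 4 tumour-derived samples, so this is no separate support. Genes detected in the control and on none of the tumour arrays fell by bounds: the carboxylesterase gene Ces2e at least 90.1-fold (adjusted p = 0.004), the TNF receptor family member and p53 target Eda2r at least 49.4-fold (0.00574), the transcriptional corepressor Runx1t1 at least 29.4-fold (0.004), the anoctamin Ano3 at least 20.4-fold (0.021) and Tnfsf4, which encodes OX40 ligand, at least 15-fold (0.0401).

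In all, 21 of 17583 genes passed in limma, 4 higher and 17 lower, and 15 of the 17 were detected in the control and on none of the tumour arrays. For these 15, Ces2e and the other bounds above among them, the measured spread is that of tumour signals near background. The lone control adds no spread, so their p-values do not measure how a detected level varies. Of 229 genes detected on the tumour side and not in the control 0 passed, against 15 of 171 the other way. With dim signals raised to a floor 6 passed higher and 43 lower. Among genes well above background on all 5 arrays, a filter that removes on/off genes, 4 passed higher and 3 lower. The excess of lower genes thus rests on genes with tumour signals near background. An unadjusted p below 0.05 was reached by 2345 genes against 879 expected by chance, and 2965 genes differed at least 2-fold, 1737 higher and 1228 lower. Among passing genes outside the naming rule, chosen after their values were seen, were the endothelial sialomucin Emcn (at least 10.9-fold lower), the carboxylesterase Ces2f (5.63-fold at least), the 5-lipoxygenase Alox5 (3.16-fold at least), the aldehyde oxidase Aox3 (1.99-fold at least) and the prolactin-family gene Prl2c3 (7.84-fold at least). Inka2 (9.07-fold), Krtap3-3 (5.44-fold) and the clone-type genes 1700007K13Rik (142-fold), 4833428L15Rik (9.07-fold) and 1700020G17Rik (6.23-fold) also passed, each value again a lower bound. Among the largest differences that did not pass were, on the higher side, the matrix protease Mmp7 (7.31 ± 1.94, adjusted p = 0.277), Tcstv3 (6.29 ± 2.03), the membrane protein Tm4sf1 (6.15 ± 0.62, 0.0931), the homeobox gene Prrx2 (5.6 ± 2.16) and the proton channel Otop2 (5.39 ± 1.40). Bounds that did not pass included at least 97.8-fold for Enpp2, which encodes autotaxin, 67.3 for Pramel39, 62.9 for the G-protein regulator Rgs16 and 35.8 for Pramel37. On the lower side were Prl2c5 (−5.96 ± 0.57, 0.0903), Dglucy (−5.66 ± 0.77), the cytochromes Cyp2c65 (−5.41 ± 1.74) and Cyp2c66 (−5.05 ± 1.22), Prl2c1 (−5.01 ± 0.42, 0.0588), gastric intrinsic factor Cblif (−4.41 ± 1.15), Pgap4 (−4.28 ± 0.65) and the xenobiotic receptor Nr1i2 (−4.14 ± 0.86). Without hairpin 1, hairpin 2 or Pik3ca, 0 genes passed in limma (2218, 2032 and 1852 with an unadjusted p below 0.05), and without Apc 19 did, 14 of them shared. With slide as a block, which leaves the contrast of shCdh1 with the control on slide 1, 0 passed (1821 unadjusted).

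Genes regulated by p53 fell together in the tumour-derived samples. Of 30 tested p53 targets, 25 were lower and the median difference was −1.34 (camera adjusted p = 1.86e-11; adjusted p = 0.205 with an estimated correlation). Over all genes 1 member passed, Eda2r, while adjusted over the list alone 19 fell and 2 rose. The largest measured differences were in the growth regulator Ddit4l (−3.99 ± 0.58), the Akt inhibitor Phlda3 (−3.84 ± 0.96), the secreted stress factor Gdf15 (−3.03 ± 0.83) and cyclin G1, Ccng1 (−2.86 ± 0.28). With slide as a block the list median was −1.26 (adjusted p = 1.93e-10). Xenobiotic and glutathione genes fell as well, 18 of 19 being lower with a median of −1.42 (adjusted p = 6.26e-10; adjusted p = 0.443 with an estimated correlation; blocked −1.65). 11 fell adjusted over the list alone and 0 over all genes. Besides Cyp2c65, the aldehyde dehydrogenase Aldh3a1 (−2.57 ± 0.29), the glutathione transferase Gsta2 (−2.54 ± 0.55) and the quinone reductase Nqo1 (−2.10 ± 0.63) were lowest.

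Markers of chief, pit and mucous neck cells were lower, while parietal and endocrine markers were not called. Chief cell markers, the genes of pepsinogen-secreting cells, had a median of −3.27 with 5 of 6 lower (adjusted p = 0.000945; adjusted p = 0.443 with an estimated correlation; blocked −2.71). 4 fell adjusted over the list alone and 0 over all genes. Cblif, pepsinogen C (Pgc, −3.33 ± 1.38), colipase (Clps, −3.22 ± 0.84) and the secretory transcription factor Bhlha15 (−2.51 ± 0.59) had the largest differences. Markers of pit cells, which cover the stomach surface with mucus, had a median of −1.51 with 10 of 11 lower (adjusted p = 0.00557; adjusted p = 0.443 with an estimated correlation; blocked −1.06). Psca, a surface antigen, was at −3.39 ± 0.95, Mucl3 at −2.03 ± 0.85, Sult1c2 at −1.60 ± 0.84 and Gkn2 at −1.52 ± 1.05, and 0 members passed over the list alone or over all genes. With normexp the pit median was −0.93. Mucous neck cell markers were lower in 8 of 8 members with a median of −0.76 (adjusted p = 0.0156; adjusted p = 0.478 with an estimated correlation; blocked −0.97), with Glipr1 at −2.08 ± 0.64 and the trefoil factor Tff2 at −1.32 ± 0.92. The median was −0.88 and −0.92 in hairpins 1 and 2, −1.73 in Pik3ca and only −0.18 in Apc, where 6 of 8 were lower and the list was not called against the control (adjusted p = 0.259). 1 fell adjusted over the list alone and 0 over all genes, and among genes well above background on all 5 arrays the call ended (−0.59, adjusted p = 0.0713).

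NF-kB and chemokine genes rose, 17 of 19 being higher with a median of 0.98 (adjusted p = 1.59e-05; adjusted p = 0.443 with an estimated correlation; blocked 1.33). 6 rose adjusted over the list alone and 0 over all genes. Tnf, the cytokine tumour necrosis factor, stood at 3.04 ± 0.48, lipocalin 2 (Lcn2) at 2.09 ± 1.34 and the NF-kB inhibitor Nfkbia at 1.24 ± 0.28. Immediate early and stress genes were higher in 16 of 17 members with a median of 0.58 (adjusted p = 0.000425; adjusted p = 0.443 with an estimated correlation; blocked 0.78). The heat shock genes Hspa1a (2.86 ± 0.69) and Hspa1b (2.36 ± 0.45) led that list, in which 0 members passed over the list alone. YAP targets had a median of 0.55 with 15 of 18 higher (adjusted p = 0.00639; adjusted p = 0.443 with an estimated correlation; blocked 0.60), led by the muscle ankyrin repeat gene Ankrd1 (3.68 ± 0.97) and the receptor kinase Axl (2.04 ± 0.83), and 0 passed over the list alone. Ras-ERK feedback genes had a median of 0.42 with 15 of 17 higher (adjusted p = 0.0135; adjusted p = 0.513 with an estimated correlation; blocked 0.49). The phosphatase genes Dusp4 (1.67 ± 0.27) and Dusp5 (1.32 ± 0.46) and the feedback inhibitor Spry4 (1.16 ± 0.45) were higher, the ligand Areg was at −1.06 ± 0.62, and 1 rose adjusted over the list alone. The Ras-ERK list had a median of 0.22 in Apc and was not called there against the control. Cell cycle genes were higher in 24 of 27 members with a median of 0.44 (adjusted p = 0.0015; adjusted p = 0.621 with an estimated correlation; blocked 0.44), including the mitotic kinases Aurka (1.14 ± 0.37) and Bub1 (1.09 ± 0.34) and the topoisomerase Top2a (1.00 ± 0.26), with 0 past the threshold over the list alone. Their median was lowest in Apc (0.20), where the list was not called against the control. YAP targets were not called in Pik3ca against the control (median 0.51).

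The 4 remaining called lists lost their call with slide as a block. Since the blocked contrast is that of shCdh1 with the control, this does not show that slide caused their shifts. Hypoxia genes, at the same 0.51, were called for shCdh1 against the control in the genotype fit. Interferon-stimulated genes, induced by antiviral signalling, were higher in 17 of 21 members with a median of 1.24 (adjusted p = 0.0135; adjusted p = 0.752 with an estimated correlation), led by the chemokine Cxcl10 (4.19 ± 0.46), the antiviral enzyme Rsad2 (3.53 ± 0.94), Ifi27l2a (2.59 ± 0.71) and Isg15 (2.53 ± 0.89). Blocked, their median was 0.42 (adjusted p = 0.223). Their median per sample was 0.28 and 0.45 in hairpins 1 and 2, 2.84 in Apc and 1.20 in Pik3ca, and without Apc it was 0.56, or 0.78 with normexp. Mesenchymal genes had a median of 1.29 with 12 of 14 higher (adjusted p = 0.0402; adjusted p = 0.478 with an estimated correlation). Fibronectin (Fn1, 3.20 ± 1.03), N-cadherin (Cdh2, 2.15 ± 1.05), vimentin (Vim, 1.98 ± 1.43) and Sparc (1.88 ± 2.22) led it, and the median per sample was 0.54, 0.63, 2.03 and 1.5 in the same order. That call ended with slide as a block (0.66), without Apc (0.76), without Pik3ca (1.44, adjusted p = 0.0681), with dim signals raised to a floor (0.73) and without the filter on dim genes (0.58, adjusted p = 0.139), and with normexp the median was 0.4 (adjusted p = 0.05). In each of these first 2 lists 1 member rose adjusted over the list alone and 0 over all genes. Hypoxia genes had a median of 0.60 with 13 of 15 higher (adjusted p = 0.0216; adjusted p = 0.752 with an estimated correlation; blocked 0.51), led by the angiogenic factor Vegfa (2.24 ± 0.59), and lost the call without Pik3ca (0.43). Their median was 0.70 and 0.39 in hairpins 1 and 2, 1.01 in Pik3ca and only 0.08 in Apc, where 9 of 15 were higher and the list was not called against the control (adjusted p = 0.608). FoxO targets had a median of 0.35 with 15 of 18 higher (adjusted p = 0.0307; adjusted p = 0.443 with an estimated correlation; blocked 0.28), led by Trib2 (2.43 ± 0.93) and cyclin G2, Ccng2 (1.77 ± 0.50), and lost the call without Apc (0.28). In both 0 passed over the list alone.

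The other 17 lists were not called, and their medians and camera adjusted p were as follows. Endocrine markers were at 1.08 (0.0563), squamous markers at 0.66 (0.0666), matrix proteases at 0.63 (0.0666), Notch targets at 0.51 (0.696), Wnt targets at 0.44 (0.381), gastric stem and progenitor markers at 0.27 (0.491) and leukocyte markers at 0.29 (0.178). Fibroblast markers were at 0.19 (0.932), glycolysis genes at 0.15 (0.243), junction and keratin genes at 0.14 (0.522), sterol and fatty acid synthesis genes at 0.14 (0.592), spasmolytic metaplasia genes at −0.06 (0.491), parietal markers at −0.08 (0.396), intestinal markers at −0.43 (0.315) and adipocyte markers at −0.44 (0.696). Endothelial markers had a median of 0.15 but a test directed downward (0.696), with Emcn the member that passed, and antigen presentation genes a median of 0.35 but a mean of −0.09 (0.932).

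**Figure D2:**
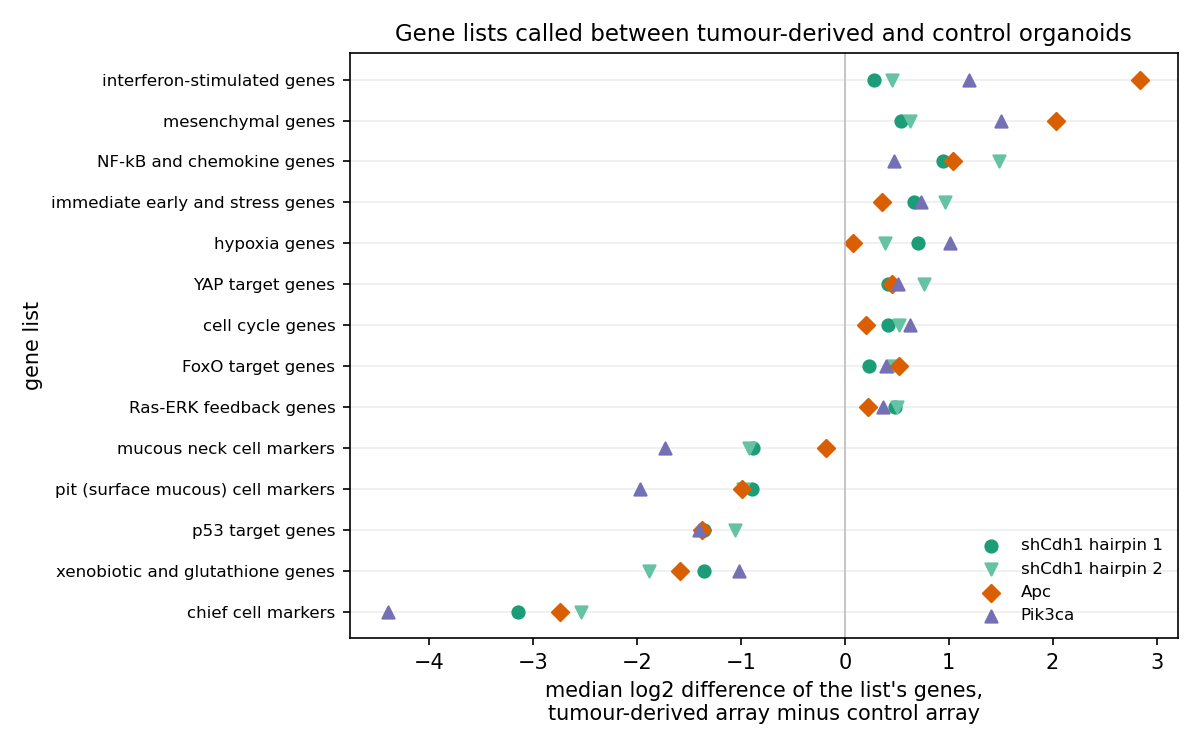
Median log2 difference of each called list's genes (horizontal axis) between each tumour-derived array and the control, 1 marker per array, for the 14 lists called in the all-tumour comparison (vertical axis). Chief cell markers lie between −4.40 and −2.54 and p53 targets between −1.40 and −1.06 in all 4 arrays, while interferon-stimulated genes range from 0.28 to 2.84.

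The second comparison set the shCdh1 tumours (n = 2) against the control, both on slide 1. Cdh1 was 18.8-fold lower (−4.23 ± 0.28, adjusted p = 0.408) and Trp53 61-fold lower (−5.93 ± 0.27, adjusted p = 0.341). Mmp7 was 88-fold higher (6.46 ± 2.03), Tm4sf1 83.5-fold (6.38 ± 0.36), Onecut1 63.4-fold (5.99 ± 0.28) and Onecut2 53.4-fold (5.74 ± 0.27). None of these differences passed. In limma 0 genes passed (lowest adjusted p = 0.341, 1712 with an unadjusted p below 0.05), a count that carries no weight against a change, since 0% of simulated changes were recovered up to 6 on the log2 scale. At least 2-fold differences were seen in 2895 genes, 1574 higher and 1321 lower. Other measured genes on the lower side were Prl2c5 (−5.84 ± 0.59), Dglucy (−5.44 ± 0.92), Cyp2c65 (−5.44 ± 2.41) and the ribosomal protein gene Rps4l (−5.39 ± 0.53). Bounds reached at least 167-fold lower for Mgmt, which encodes a DNA repair methyltransferase, 84.7 for Ces2e, 46.4 for Eda2r, 37.1 for the cholecystokinin receptor Cckar and 32.4 for Zfp365. On the higher side they reached at least 68.3-fold for Enpp2, 46.8 for Rgs16, 34.1 for the homeobox gene Esx1 and 27.3 for Pramel39.

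In the shCdh1 tumours 11 lists were called, 6 up and 5 down, and each had an adjusted p of 0.586 with an estimated correlation, or 0.637 for hypoxia genes. p53 targets fell (median −1.26, 25 of 30 lower, camera adjusted p = 1.19e-09), with Phlda3 at −4.72 ± 0.51 and Ddit4l at −4.16 ± 0.64, and adjusted over the list alone 11 fell and 1 rose. Xenobiotic and glutathione genes (−1.65, adjusted p = 1.31e-09), chief markers (−2.71, 4.69e-05), pit markers (−1.06, 0.00152) and mucous neck markers (−0.97, 0.00247) fell too. Adjusted over the list alone 6 xenobiotic and 5 chief cell genes fell, Cblif being at −4.70 ± 0.78. NF-kB and chemokine genes rose (1.33, 18 of 19 higher, adjusted p = 2.61e-05, Tnf 3.35 ± 0.52), as did immediate early and stress genes (0.78, 4.69e-05), among them Hspa1a (2.62 ± 0.84) and the stress transcription factor Ddit3 (1.92 ± 0.28). Cell cycle genes (0.44, adjusted p = 0.00121), Ras-ERK feedback genes (0.49, 0.00247, Dusp4 1.82 ± 0.29), hypoxia genes (0.51, 0.0121, Vegfa 2.26 ± 0.46) and YAP targets (0.60, 0.021, Ankrd1 4.09 ± 1.23) rose as well. Without the filter on dim genes the YAP call ended (adjusted p = 0.0764). With normexp the medians of pit markers, mucous neck markers and NF-kB and chemokine genes were −0.67, −0.64 and 0.8. Despite the lower Cdh1, junction and keratin genes as a list had a median of 0.08 (adjusted p = 0.78), and mesenchymal genes one of 0.66 (0.0897). Over all genes 0 members of any list passed.

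The third comparison set the Apc tumour against the control. Ptn, which encodes the growth factor pleiotrophin, was 170-fold higher (7.41 ± 0.39, adjusted p = 0.21), Bex1 297-fold (8.21 ± 1.74, 0.459), Tcstv3 273-fold (8.09 ± 2.14) and the serine protease Htra1 132-fold (7.04 ± 1.00). Trp53 was 105-fold lower (−6.72 ± 0.31, adjusted p = 0.21). None of these passed. In limma 0 genes passed (lowest adjusted p = 0.21, 1586 unadjusted), where 0% of simulated changes were recovered, and 3131 genes differed at least 2-fold, 1990 higher and 1141 lower. Bounds reached at least 350-fold higher for Bex4, 312 for the secreted Wnt modulator Dkk3, 262 for peroxidasin (Pxdn), 202 for Pramel39 and 154 for the transcription cofactor Lmo2. Lower were Dglucy (−6.36 ± 1.06), Prl2c5 (−5.58 ± 0.69), the carboxylesterase Ces1f (−5.13 ± 0.99) and Cyp2c65 (−4.88 ± 2.79), and by bounds Ces2e (at least 107-fold), Eda2r (58.5), Runx1t1 (34.9), Cyp2d37-ps (32) and Ms4a10 (25.9). Apc and control arrays were on different slides, so slide and genotype cannot be told apart here.

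In the Apc tumour 13 lists were called against the control, 8 up and 5 down, each with an adjusted p of 0.728 with an estimated correlation, or 0.816 for intestinal markers. Wnt targets rose with a median of 1.36, 19 of 22 being higher and 13 at least 2-fold (camera adjusted p = 1.47e-06). 5 rose adjusted over the list alone and 0 over all genes. The feedback genes Apcdd1 (6.27 ± 1.73), Nkd1 (5.40 ± 3.89) and Axin2 (2.32 ± 0.79) and the transcription factor Tcf7 (1.86 ± 0.31) had the largest differences. Interferon-stimulated genes were higher in 20 of 21 members with a median of 2.84 (adjusted p = 3.54e-12), and adjusted over the list alone 11 rose, among them Rsad2 (5.10 ± 0.36), the ISG15 protease Usp18 (5.04 ± 0.42), Cxcl10 (4.83 ± 0.43) and Ifit1 (3.89 ± 0.32). Mesenchymal genes rose (2.03, adjusted p = 0.000654), with Sparc at 5.59 ± 0.59, Fn1 at 4.41 ± 1.22 and Vim at 3.88 ± 0.35 and 3 members past the threshold adjusted over the list alone. NF-kB and chemokine genes (1.04, adjusted p = 9.21e-06, Lcn2 3.64 ± 1.52, Ccl2 3.48 ± 0.81), YAP targets (0.45, 0.00741), squamous markers (0.55, 0.0233, Krt17 3.16 ± 0.42), FoxO targets (0.52, 0.0407) and immediate early and stress genes (0.36, 0.0407) rose. p53 targets (−1.37, adjusted p = 3.85e-09), xenobiotic and glutathione genes (−1.59, 5.26e-08), chief markers (−2.74, 0.000349), pit markers (−0.99, 0.0163) and intestinal markers (−0.69, 0.0233) fell, although the intestinal keratin Krt20 was at 3.36 ± 1.93. Fibroblast markers were not called (0.84, adjusted p = 0.185), with 4 of 8 higher, each at least 2-fold, and 2 past the threshold adjusted over the list alone. Adjusted over the list alone 3 squamous genes rose, 3 p53 targets fell, 2 xenobiotic genes fell, and 1 chief and 1 intestinal marker fell. Without the filter on dim genes the calls of chief markers (−1.59, adjusted p = 0.179) and pit markers (−0.99, 0.0672) ended, as did that of intestinal markers among genes well above background on all 5 arrays (−0.69, 0.0737) and that of immediate early and stress genes with the mean over probes (0.31, 0.0542). With normexp the medians of mesenchymal and interferon-stimulated genes were 0.79 and 1.78.

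The fourth comparison set the Pik3ca tumour against the control. Mmp7 was 738-fold higher (9.53 ± 2.35, adjusted p = 0.389), the neuronal enolase Eno2 362-fold (8.50 ± 1.15, 0.312), Tcstv3 186-fold (7.54 ± 2.14) and Otop2 163-fold (7.34 ± 1.32). Cym, which encodes the milk-clotting protease chymosin, was 572-fold lower (−9.16 ± 2.13, adjusted p = 0.382) and Trp53 52.3-fold lower (−5.71 ± 0.31). None of these passed. In limma 0 genes passed (lowest adjusted p = 0.298, 2030 unadjusted), and 3880 genes differed at least 2-fold, 2119 higher and 1761 lower. Also lower were Xlr4b (−7.01 ± 4.26), Prl2c5 (−6.60 ± 0.69) and Cyp2c65 (−5.88 ± 2.79). Bounds reached at least 205-fold higher for Enpp2, 171 for Eif2s3y, 136 for Pramel39, 132 for Rgs16 and 123 for the intestinal cadherin Cdh17, and lower for Xlr3b (at least 209-fold), Mgmt (170), Ces2e (86.2), Eda2r (47.3) and the phospholipase Pla2g4c (43.8). Y-linked Eif2s3y stands in this contrast beside the Xist and Y-gene levels given above for this sample, and slide and genotype cannot be told apart. The X-linked Xlr3a was at −8.24 in Pik3ca, −7.94 and −8.22 in hairpins 1 and 2, −4.18 in Apc and −2.07 in the control. Its low level was thus not particular to the sample with male-type markers.

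In the Pik3ca tumour 16 lists were called against the control, 11 up and 5 down, each with an adjusted p of 0.635 with an estimated correlation, or 0.945 for glycolysis genes. Hypoxia genes were higher in 15 of 15 members with a median of 1.01 (camera adjusted p = 2.05e-05), with Vegfa at 2.91 ± 0.53 and Ndrg1 at 2.00 ± 0.62. Glycolysis genes were higher in 17 of 17 members with a median of 0.28 (adjusted p = 0.0338), led by the lactate transporter Slc16a3 (1.42 ± 0.40), but the call ended under quantile normalization (0.21). Squamous markers rose (1.03, adjusted p = 0.00339), with the keratins Krt14 at 4.28 ± 0.33 and Krt6a at 2.92 ± 0.31 and the desmosome gene Pkp1 at 4.15 ± 0.54, and 4 members rose adjusted over the list alone. Chief markers were lower in 6 of 6 members (−4.40, adjusted p = 1.46e-05), with Pgc at −5.52 ± 0.81 and Cblif at −5.46 ± 0.90 and 5 past the threshold adjusted over the list alone. Pit markers (−1.97, adjusted p = 0.00305, Psca −4.53 ± 1.1, Ctse −2.77 ± 0.47), mucous neck markers (−1.73, 0.000731), p53 targets (−1.40, 6.14e-08) and xenobiotic and glutathione genes (−1.02, 0.000108) fell. Interferon-stimulated genes (1.20, adjusted p = 6.26e-05, Cxcl10 3.93 ± 0.43), cell cycle genes (0.63, 0.000459), immediate early and stress genes (0.73, 0.00135), mesenchymal genes (1.5, 0.00582, Vim 2.77 ± 0.35), NF-kB and chemokine genes (0.47, 0.0126), Ras-ERK feedback genes (0.37, 0.0338), endocrine markers (1.09, 0.0345, Cpe 3.43 ± 1.91, Chga 1.56 ± 1.16) and FoxO targets (0.40, 0.0458, Trib2 3.78 ± 0.60) rose. 5 interferon-stimulated genes and 1 xenobiotic gene rose, and 1 p53 target, 1 pit marker and 2 xenobiotic genes fell adjusted over the list alone, and over all genes 0 members of any list passed. The endocrine call held in 4 of 9 alternatives, ending for example among genes well above background on all 5 arrays (0.71, adjusted p = 0.249) and with normexp (0.26, 0.128). Without the filter on dim genes the calls of mesenchymal genes (0.79, 0.0809) and FoxO targets (0.4, 0.0809) ended, the latter also with a floor (0.0581), and among genes well above background on all 5 arrays that of NF-kB and chemokine genes did (0.42, 0.0796). Medians that moved by over 1.5 times with the call kept were mesenchymal genes (0.91), mucous neck markers (−0.81), squamous markers (0.56) and interferon-stimulated genes (0.76) with normexp, glycolysis genes with the mean over probes (0.43), chief markers without the filter (−2.9), and squamous markers without the filter (0.55) and among genes well above background on all 5 arrays (0.62).

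All 4 tumour-derived arrays lay at least 2-fold above the control in 556 genes and at least 2-fold below it in 487, of which 254 and 324 were well above background on all 5 arrays. With 1 control shared by the 4 contrasts and no change simulated, 138 and 143 genes did so on average over 20 draws, and independent lists of the observed sizes would share 2 and 1. Those draws gave the control the same spread as the tumours. Taking another array as the reference gave 292 genes in all for hairpin 1, 327 for hairpin 2, 552 for Apc and 466 for Pik3ca, against 1043 for the control. The single control enters all 4 contrasts, so its own deviations count in each of them.

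The fifth comparison asked what set the shCdh1 tumours apart from the Apc and Pik3ca tumours. Cdh1 was 20.7-fold lower (−4.37 ± 0.23, adjusted p = 0.477). Serpinh1, which encodes a collagen chaperone, was 31.4-fold lower (−4.97 ± 0.27, 0.477), Ptn 22.1-fold (−4.47 ± 0.28, 0.477), Rps4l 78.6-fold (−6.30 ± 0.43, 0.477) and the glycosyltransferase B4galnt2 11.9-fold (−3.57 ± 1.1). Higher were Bcl2a1d (2.76 ± 1.08), Itih2 (2.63 ± 0.38), the chemokine Ccl20 (2.26 ± 0.78), Ptprn (2.07 ± 0.57) and Nckap5 (2.00 ± 0.22). None passed. In limma 0 genes passed (lowest adjusted p = 0.477, 1060 unadjusted against 879 expected by chance), and 1569 differed at least 2-fold, 441 higher and 1128 lower. Bounds reached at least 119-fold lower for the homeobox gene Pitx1, 23.6 for Pxdn, 16.1 for the transcription factor Sox11, 13.6 for the glucose transporter Slc2a3 and 12.8 for the neurotrophin receptor Ngfr, and at least 2.5-fold higher for Nrip2, 2.42 for Pp2d1, 2.34 for Olfr649, 2.33 for A1cf and 2.25 for Cstdc1.

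4 lists were called in the shCdh1 tumours against the others, all lower, each with an adjusted p of 0.962 with an estimated correlation. Interferon-stimulated genes were lower in 21 of 21 members (median −1.34, camera adjusted p = 1.63e-14), with Rtp4 at −2.43 ± 0.23, Usp18 at −2.10 ± 0.29 and Ifit1 at −1.96 ± 0.23, and adjusted over the list alone 11 were lower. Without Apc the median was −0.56. Wnt targets were lower in 20 of 22 members (−0.81, adjusted p = 8.3e-09), with Apcdd1 at −2.77 ± 1.23 and Axin2 at −1.95 ± 0.56. The call ended without Apc (−0.13, adjusted p = 0.288), and without Pik3ca the median was −1.52. Squamous markers were lower (−0.90, adjusted p = 0.000472), with Krt14 at −2.57 ± 0.23 and Krt17 at −1.85 ± 0.30, a call that ended without Pik3ca (−0.28, adjusted p = 0.0726). The squamous median was −0.25 with normexp, −0.24 among genes well above background on all 5 arrays and −0.51 without the filter on dim genes. Mesenchymal genes were lower (−0.49, adjusted p = 0.0138), with Sparc at −3.10 ± 0.42 and Vim at −2.70 ± 0.24, while 5 of 14 members were higher. That call ended without Apc (−0.08) and without the filter on dim genes (−0.24, adjusted p = 0.0604), and the median was −1.38 without Pik3ca and −0.26 with normexp. 2 mesenchymal, 1 Wnt and 1 squamous gene passed adjusted over the list alone, and over all genes 0. Junction and keratin genes had a median of −0.09 (adjusted p = 0.603). The shCdh1 and other tumours were on different slides, so slide and genotype cannot be told apart.

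The sixth comparison asked what set the Apc tumour apart from the shCdh1 and Pik3ca tumours. Ptn was 67.4-fold higher (6.07 ± 0.33, adjusted p = 0.225), Cym 200-fold (7.65 ± 1.77, 0.67), the Wnt feedback gene Nkd1 79.8-fold (6.32 ± 3.23), the ligand Wnt6 58.3-fold (5.86 ± 2.77) and Bex1 53-fold (5.73 ± 1.44). Lower were the steroid dehydrogenase Hsd17b2 (−5.37 ± 0.78), Rhox5 (−5.18 ± 4.05), the brush border myosin Myo7b (−5.06 ± 1.14), the lipoxygenase Alox12b (−3.79 ± 0.89) and endothelin 2, Edn2 (−3.64 ± 0.47). None passed. In limma 0 genes passed (lowest adjusted p = 0.223, 1060 unadjusted), where 0% of simulated changes were recovered, and 1982 differed at least 2-fold, 1329 higher and 653 lower. Bounds reached at least 314-fold higher for Bex4, 89.2 for the Wnt modulator Dkk2, 64.4 for Lce1i, 58.5 for Pid1 and 47.5 for Gxylt2, and lower for Foxn4 (at least 12.6-fold), the gastric homeobox gene Nkx6-3 (11.8), Ugt1a10 (11.1), Gabrd (3.74) and Rasal1 (3.19). With normexp background correction 10 genes passed, all higher.

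13 lists were called in the Apc tumour against the others, 6 up and 7 down, each with an adjusted p of 0.858 with an estimated correlation. Wnt targets were higher in 18 of 22 members, 13 of them at least 2-fold (median 1.33, camera adjusted p = 3.91e-09; 1.23 within slide 2). 4 rose adjusted over the list alone, and Apcdd1 stood at 3.88 ± 1.44, the transcription factor Sp5 at 2.66 ± 0.53 and Axin2 at 2.44 ± 0.66. Interferon-stimulated genes were higher in 21 of 21 members (1.17, adjusted p = 7.42e-14; 0.90 within slide 2, adjusted p = 1.1e-07), with Usp18 at 3.91 ± 0.35 and Rtp4 at 2.49 ± 0.27 and 11 past the threshold adjusted over the list alone. Leukocyte markers had a median of −0.28 in the same contrast. Mesenchymal genes were higher (0.83, adjusted p = 0.00988, Sparc 4.79 ± 0.49), but not past the threshold within slide 2 (0.71, adjusted p = 0.16), and the median was 1.38 without Pik3ca, 0.18 with normexp and 0.49 with a floor. Chief markers (1.18, adjusted p = 0.00154, Cblif 2.31 ± 0.75; 1.51 within slide 2) and mucous neck markers (0.79, 0.00765, Tff2 1.69 ± 0.36, Muc6 1.66 ± 0.63; 1.21 within slide 2) were higher, and both calls ended without Pik3ca (0.39, adjusted p = 0.0973, and 0.79, adjusted p = 0.0726). With normexp the chief median was 0.67, and among genes well above background on all 5 arrays the Wnt median was 0.81. Fibroblast markers were higher (0.68, adjusted p = 0.018; 0.56 within slide 2) but kept the call in 5 of 10 alternatives. It ended with normexp (0.18, 0.193), quantile normalization (0.64, 0.0502), no filter on dim genes (0.31, 0.157) and the mean over probes (0.65, 0.0769), and among genes well above background on all 5 arrays the median was −0.33 (0.6). Adjusted over the list alone 2 mesenchymal genes and 1 chief and 1 fibroblast marker rose, and over all genes 0 members of any list passed.

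Among the lists lower in the Apc tumour, hypoxia genes were lower in 15 of 15 members (median −0.79, adjusted p = 1.85e-05; −1.05 within slide 2), with Ankrd37 at −1.40 ± 0.35 and Ndrg1 at −1.29 ± 0.51, and the median without Pik3ca was −0.47. Glycolysis genes were lower in 17 of 17 members (−0.42, adjusted p = 0.00127; −0.51 within slide 2), a call that ended under quantile normalization (−0.21, adjusted p = 0.116). Sterol and fatty acid synthesis genes (−0.52, adjusted p = 0.000978, Hmgcs1 −0.91 ± 0.43; −0.59 within slide 2) and cell cycle genes (−0.32, 0.000978, Rrm2 −1.32 ± 0.26; −0.44 within slide 2) were lower. So were immediate early and stress genes (−0.48, 0.0047, Fos −1 ± 0.27; −0.36 within slide 2) and Ras-ERK feedback genes (−0.31, 0.0289; −0.24 within slide 2, adjusted p = 0.174). Intestinal markers were lower (−0.83, adjusted p = 0.00988; −1.16 within slide 2), with the intestinal homeobox gene Cdx2 at −2.55 ± 0.95 while the lysozyme gene Lyz1 was at 2.28 ± 0.66, and the call ended without Pik3ca (−0.29, adjusted p = 0.311) and without the filter on dim genes (−0.75, 0.122), with −0.45 under normexp. The Ras-ERK call also ended without that filter (adjusted p = 0.122). Quantile normalization gave −0.34 for sterol and fatty acid synthesis genes, −0.14 for cell cycle genes and −0.29 for immediate early and stress genes, the last being at −0.27 with normexp.

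**Figure D3:**
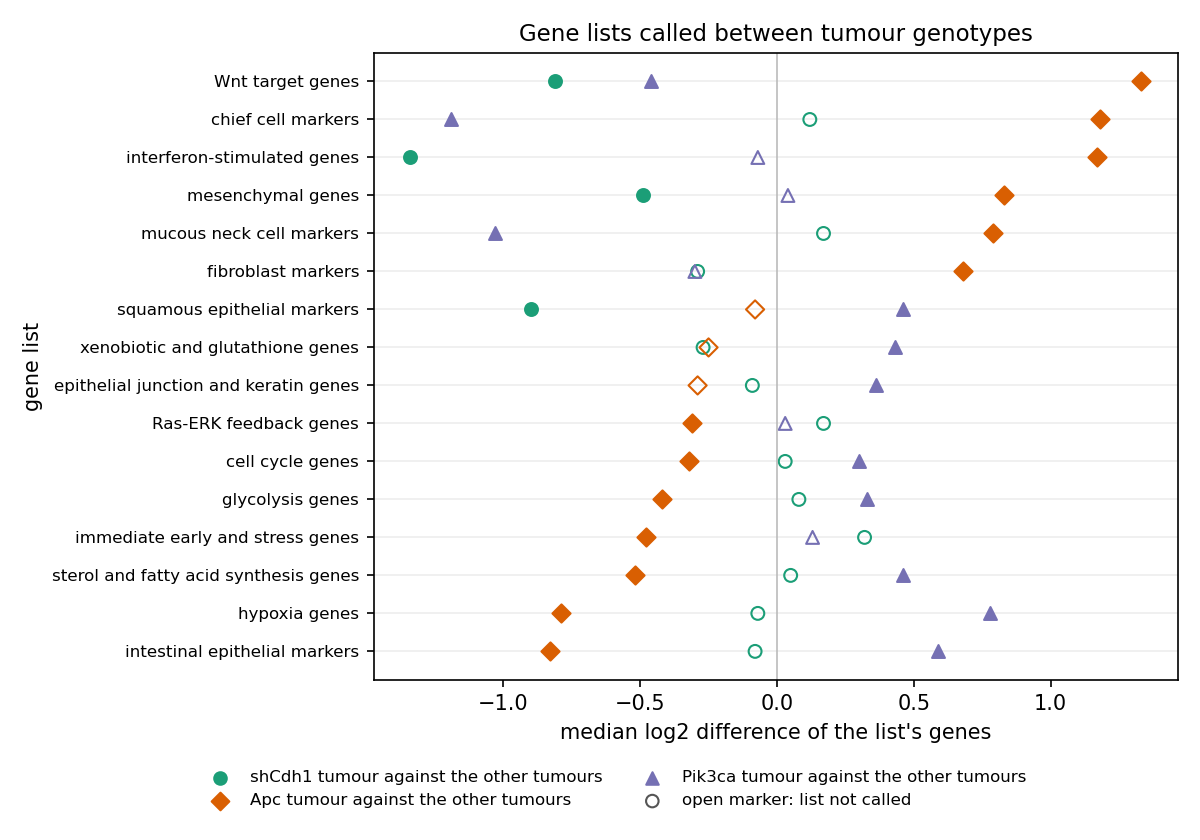
Median log2 difference of each list's genes (horizontal axis) in the shCdh1, Apc and Pik3ca tumours, each against the other tumour genotypes, for lists called in at least 1 of these comparisons (vertical axis). Filled markers are called lists and open markers are not; Wnt targets lie at 1.33 in Apc, −0.81 in shCdh1 and −0.46 in Pik3ca, and hypoxia genes at 0.78 in Pik3ca and −0.79 in Apc.

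The seventh comparison asked what set the Pik3ca tumour apart from the shCdh1 and Apc tumours. Rps4l was 68.1-fold higher (6.09 ± 0.51, adjusted p = 0.631), Rhox5 65.3-fold (6.03 ± 4.05), the lectin-like receptor gene Klra16 52.9-fold (5.73 ± 0.30), Eno2 46.5-fold (5.54 ± 0.95) and the proteoglycan serglycin, Srgn, 39.1-fold (5.29 ± 0.50). Lower were Cym (185-fold, −7.53 ± 1.77), the kinase Rps6ka6 (−4.43 ± 1.91), Wnt6 (−4.37 ± 2.77), Nkd1 (−3.91 ± 3.23) and Mtus2 (−3.30 ± 1.51). None passed. In limma 0 genes passed (lowest adjusted p = 0.606, 1008 unadjusted), and 1843 differed at least 2-fold, 843 higher and 1000 lower. The largest bounds were sex-linked: at least 171-fold higher for Eif2s3y, 18.5 for Kdm5d and 12.6 for Ddx3y, and at least 36-fold lower for Xist. Hyaluronan synthase Has2 (at least 10.2-fold) and Scin (10.1) were also higher, and Samt1c (7.96), Pla2g4c (7.01), albumin (Alb, 5.34) and Abca8b (5.13) lower.

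11 lists were called in the Pik3ca tumour against the others, 8 up and 3 down, each with an adjusted p of 0.788 with an estimated correlation. Hypoxia genes were higher in 15 of 15 members (median 0.78, camera adjusted p = 3.52e-07; 1.05 within slide 2; 0.49 without Apc), with Ndrg1 at 1.67 ± 0.51 and the vasodilator peptide gene Adm at 1.33 ± 0.26. Junction and keratin genes were higher in 22 of 25 members (0.36, adjusted p = 0.0019; 0.35 within slide 2), led by Cdh1 (2.26 ± 0.27), which is lowered in the shCdh1 part of the comparator, and the claudin Cldn3 (2.05 ± 0.30). Intestinal markers were higher (0.59, adjusted p = 0.00224; 1.16 within slide 2), with the trefoil factor Tff3 at 2.87 ± 1.20, Cdx2 at 2.63 ± 0.95 and Muc13 at 1.69 ± 0.41, while Lyz1 was at −2.46 ± 0.66. Squamous markers were higher (0.46, adjusted p = 0.00296, Krt14 2.56 ± 0.27, Krt6a 2.25 ± 0.26; 0.25 within slide 2, adjusted p = 0.0848; 0.95 without Apc), as were xenobiotic and glutathione genes (0.43, 0.0121; 0.32 within slide 2, adjusted p = 0.0549). Sterol and fatty acid synthesis genes (0.46, adjusted p = 0.0019; 0.59 within slide 2), glycolysis genes (0.33, 0.00453; 0.51 within slide 2) and cell cycle genes (0.30, 0.00224; 0.44 within slide 2) were higher, and without Apc these calls ended at 0.24, 0.14 and 0.20. Quantile normalization ended the calls of glycolysis genes (0.18, adjusted p = 0.0667), cell cycle genes (0.18, 0.0532) and xenobiotic and glutathione genes (0.25, 0.0636), and gave 0.3 for sterol and fatty acid synthesis genes and 0.22 for junction and keratin genes. Without the filter on dim genes the calls of squamous markers (0.42, 0.0756) and xenobiotic and glutathione genes (0.43, 0.0532) ended, and the squamous median was 0.28 with normexp and 0.27 among genes well above background on all 5 arrays.

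Chief markers were lower in the Pik3ca tumour in 6 of 6 members (−1.19, adjusted p = 0.00252, Pgc −2.86 ± 0.67; −1.51 within slide 2), as were mucous neck markers (−1.03, adjusted p = 0.0137, Tff2 −1.97 ± 0.36; −1.21 within slide 2). Without Apc both calls ended, at −0.94 and −0.77. Wnt targets were lower (−0.46, adjusted p = 0.00862; −1.23 within slide 2), but without Apc their median was 0.13, and among genes well above background on all 5 arrays the call ended (−0.3, adjusted p = 0.561). Adjusted over the list alone 2 squamous genes and 1 intestinal marker rose and 2 Wnt targets fell in this comparison, and over all genes 0 members of any list passed.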

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

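All tests of explanations in this part were chosen after the results were seen. 3 kinds of result stood out: a sample apart from the other tumour-derived samples, a gene list that differed between genotypes, and signal in probes without a gene name.

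Interferon-stimulated genes differed between the genotypes, with medians of 1.17 in the Apc tumour and −1.34 in the shCdh1 tumours, each against the other tumours and neither called with an estimated correlation. Apc and Pik3ca arrays shared slide 2, and there the list was higher in Apc by 0.9, in 19 of 21 members, which argues against a difference between slides as the whole cause. Leukocytes as the direct source of these transcripts in the Apc sample would be expected to raise their own markers at least as much. The list's median exceeded that of leukocyte markers by 1.45, leukocyte markers lying at −0.28 with 4 of 11 higher. Some of these markers lay near background, such as Cd52 at −6.02 in Apc, so a small admixture is not excluded. Of these markers Coro1a was at −2.41 in Apc and between −2.87 and −2.43 in the other tumours, and Ptprc at −4.63 against −6.1 to −4.75. What raised these genes in the Apc tumour stays open, since the difference rests on 1 array. A response of the epithelial cells to interferon, infection of the culture, culture state and differences between animals were not tested.

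The other differences between genotypes, each a camera test of the difference itself and none called with an estimated correlation, were as follows. In the shCdh1 tumours mesenchymal genes had a median of −0.49, Wnt targets −0.81 and squamous markers −0.9. In the Apc tumour mesenchymal genes stood at 0.83, Wnt targets at 1.33, mucous neck markers at 0.79, chief markers at 1.18 and fibroblast markers at 0.68. Lower in the Apc tumour were sterol and fatty acid synthesis genes (−0.52), glycolysis genes (−0.42), hypoxia genes (−0.79), cell cycle genes (−0.32), intestinal markers (−0.83), immediate early and stress genes (−0.48) and Ras-ERK feedback genes (−0.31). In the Pik3ca tumour junction and keratin genes stood at 0.36, sterol and fatty acid synthesis genes at 0.46, glycolysis genes at 0.33, hypoxia genes at 0.78, cell cycle genes at 0.3, intestinal markers at 0.59, squamous markers at 0.46 and xenobiotic and glutathione genes at 0.43. Lower there were Wnt targets (−0.46), mucous neck markers (−1.03) and chief markers (−1.19). Since each genotype is set against the other 2, these differences are not independent of one another.

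3 of 23 values tested had 1 tumour-derived sample apart from the other 3 by Dixon's 95% criterion on the ratio of gap to range, where about 1 in 20, or 1.1, would be by chance. The median of p53 targets was −1.06 in hairpin 2 and between −1.4 and −1.35 in the others (ratio 0.844). The median of pit markers was −1.97 in Pik3ca and between −0.99 and −0.89 in the others (ratio 0.905). The Onecut2 level was 4.22 in Pik3ca and between 3.97 and 4.01 in the others (ratio 0.83).

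Of 22024 probes without a gene name, 13183 were well above background on at least 1 array. Among them 326 were well above background on all 4 tumour-derived arrays and at least 2-fold above the control on each, and 222 were well above background on the control and at least 2-fold below it on each. With another array as the reference for the other 4, the 2 counts were 47 and 112 for hairpin 1, 42 and 118 for hairpin 2, 24 and 184 for Apc and 60 and 131 for Pik3ca. The single control enters all 4 differences, so its own deviations count in each of them.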

How the results depend on the processing

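Each result was recomputed with 1 choice changed at a time, except that normexp changes the signal, its spatial detrending and the background correction together, so that its effects cannot be credited to any of these alone. Slide as a random block and the differences within slide 2 were chosen after the data had been seen. The shifts of called lists kept direction and call in 801 recomputations, lost the call in 55 and reversed in 2. Some of the 801 could not have changed. In the genotype fit, leaving out Apc or Pik3ca does not alter the contrast of another genotype with the control. Fitting only the shCdh1 and control arrays does not alter theirs either. Of 243 named gene results 21 had passed in the main setting. For named genes, direction and outcome, passed or not, stayed the same in 2607 recomputations. Most of these are genes that did not pass in either setting, so that number does not measure how often a call was kept. A call was lost in 135 and gained in 18, and the direction reversed in 5. Counts and targeted genes stayed within their limits in 163 recomputations and moved in 25. Many of the 163 are counts of 0 passing genes in the genotype fit that stayed at 0. That fit recovered 0% of changes where it was simulated, so these counts could hardly move and are no sign of stability.

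Against the main count of 21 genes in all tumour-derived samples, 49 passed with normexp, 49 with a floor and 7 among genes well above background on all 5 arrays, a filter that removes on/off genes. 14, 19 and 6 of these were shared with the 21. In limma 0 passed with slide as a block and 0 in the genotype fit (1821 and 2162 with an unadjusted p below 0.05), both with fewer residual degrees of freedom, while 20 passed with slide as a random block, all shared with the 21, and leaving out 1 sample gave 0 to 19. Onecut1 (4.39 to 6.07), Onecut2 (5.58 to 5.84) and Trp53 (−6.19 to −4.16) kept their calls in 11 of 16 alternatives, and Otop3 (3.76 to 5.8), Cdkn2a (3.75 to 4.01) and Ak1 (−5.31 to −4.41) in 10 of 16. The passing genes given as bounds kept theirs in 5 of 15 (Aox3 and Inka2), 6 of 15 (Alox5) or 7 of 15 (Ces2f), up to 10 of 15 (Ces2e among others). With normexp 10 genes passed for Apc against the other tumours. With an estimated correlation, where camera has little power at these residual degrees of freedom, 0 lists were called in each of the 7 comparisons. By random lists 20 were called for shCdh1 against control (11 by camera at the preset correlation) and 11 for shCdh1 against the other tumours (4 by camera). Leaving out Apc or Pik3ca gave 6 to 10 called lists for shCdh1 against the other tumours, and leaving out Apc gave 6 in place of 11 for Pik3ca against the other tumours.

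With normexp Cdh1 in shCdh1 tumours minus control moved from −4.23 to −4.04, Trp53 in all tumour-derived samples from −6.07 to −4.16, and Apc in the Apc tumour from −0.35 to −0.21, or to −0.53 with quantile normalization. The genes at least 2-fold apart between the hairpins went from 2325 to 801 with normexp. 7 values reversed, none of the genes having passed. Trp53 in shCdh1 against the other tumours (0.28) was −0.22 without Apc and 0.78 without Pik3ca. Within slide 2, Cdh1 in Apc was −0.1, the shCdh1 arrays being absent there, and the Apc gene 0.12, with 0.02 under normexp. The Pik3ca gene in the Pik3ca tumour was −0.42 without Apc. Fibroblast markers in Apc (0.68) were at −0.33 among genes well above background on all 5 arrays, and Wnt targets in Pik3ca (−0.46) at 0.13 without Apc, whose comparator then holds no Apc tumour. Where no construction is named, the cause was not tested.

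Leaving out a hairpin in the genotype fit was not run for lack of residual degrees of freedom, nor was a slide block for single genotypes, each genotype lying on 1 slide. No paired analysis was possible because the samples share no animal or culture number. Signal over background, 24 to 27.9 times at the 75th percentile, limits genes near background, for which only bounds are given. The median of all genes shifted by 0.111 without the filter and by 0.065 in the main setting.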

Other observations

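The tests of the sex markers and of Trp53 loss were chosen after the results were seen, as were the 11 further lists and the genes named here. Only the test of shared signal was written beforehand, and the split of its genes by family was added after its result was seen. Some genes of the 2-cell embryo lay far above the control in tumour-derived samples, though no member of the Zscan4, Pramel and other 2-cell lists passed in limma. The median of 4 Zscan4 genes, which act in telomere maintenance and the 2-cell stage, was 5.19, and per sample 5.47 and 1.88 with hairpins 1 and 2, 6.89 in Apc and 6.5 in Pik3ca. Zscan4a and Zscan4c were not well above background in the control, and with such levels raised to the lowest signal well above background these medians were 4.55 (4.81, 1.34, 6.22 and 5.87). 15 Pramel genes had a median of 2.02 (1.99, 0.23, 3.25 and 2.94 in the same order), or 1.27 with levels so raised, 10 being at least 2-fold higher, while Pramel12 (−0.07), Pramel15 (−0.2), Pramel25 (−0.03) and Pramel26 (−0.48) were not. 15 other 2-cell genes had a median of 1.51 (0.15 in hairpin 2), or 0.84 with levels so raised, which does not settle whether near-identical family members share signal, since 8 of them belong to the Usp17l and Tdpoz families, which hold 7 of the 9 that were at least 2-fold higher. The 6 outside these families that were well above background on at least 1 array had a median of 0.13, with BB287469 at 4.6 and Tmem92 at 1.02 but Zfp352 at 0.01, Sp110 at 0.03, Chit1 at −0.02 and Arg2 at 0.24. Tcstv3, left off the list because its value had been seen, was at 6.29 and well above background on all 5 arrays, so shared signal stays open. Trp53 loss as the whole cause stays open as well, being confounded with growth as a tumour. The Zscan4 median was lowest in hairpin 2, where the Pramel and other medians stayed near the control although Trp53 was as low there as in hairpin 1.

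Some single genes, picked because they differed widely among the tumour-derived samples, are given without a test of spread and stand for no group of genes. The X-linked homeobox gene Rhox5 was at 7.02 and 7.42 in hairpin 1 and Pik3ca and at −1.37 and −0.06 in hairpin 2 and Apc, a 440-fold range, against 1.4 in the control. Prox1 was at 1.26 in Apc and −1.65 in hairpin 2 and not well above background in hairpin 1 and Pik3ca. Pitx1, a homeobox gene of the hindlimb and oral epithelium, stood at 2.19 in Pik3ca, −0.21 in Apc and −1.85 in the control and was not detected in either shCdh1 array. Irx2 was at −1.11 and −1.65 in hairpin 2 and Apc and not well above background in hairpin 1 and Pik3ca. Ndn was at 0.58 in Apc, −3.36 in Pik3ca and −4.16 in hairpin 2 and not well above background in hairpin 1.

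The sample labelled Pik3ca carried male-type sex markers although its label says female. Cells of a male animal mixed into a female sample would leave Xist near the others. It was not well above background here, and raised to the lowest signal that was, it still lay at −5.02 relative to the lowest of the others, which argues against a mixture with a large share of female cells. Loss of the inactive X in a female sample is argued against by 4 Y-linked genes well above background here and in none of the other 4 samples. The fifth tested, Zfy2, was not well above background here (−7.27) but was in hairpin 2 alone (−5.58). A male animal behind this sample, so that the sex label is wrong for it, is a candidate explanation that these 4 genes and Xist leave standing. Whether other labels of the sample are affected was not tested, and sex is then mixed with genotype for sex-linked genes in its comparisons.

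The remaining lists written after values were seen had these medians in tumour-derived samples minus control. Y-linked genes, none well above background in the control, were at 1.69, with 0.25, 0.21, −0.11 and 5.87 in hairpins 1 and 2, Apc and Pik3ca, and with levels raised as above at 0.96, with 3.66 in Pik3ca. Imprinted genes were at 0.48, Hox genes at 0.42, foregut regional transcription factors at 0.14, germ cell genes at 0.22 and ribosomal protein genes at 0.04. With levels so raised, Hox genes were at 0.14 and imprinted genes at 0.4. The list of Ink4 and Arf genes, which includes the related Cdkn2d (1.19), was at 0.67, with Cdkn2b also at 0.67. The prolactin family list holds 4 tested genes, of which Prl2c1 (−5.01), Prl2c3 (−4.89, not well above background in the tumour-derived samples) and Prl2c5 (−5.96) had been seen to fall before it was written, while Prl3d1 was at −0.21.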
